A study of Mus musculus with 14 samples.

How the data were processed

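Bone marrow cells that were positive for Sca1 and negative for Kit were sorted from young and old female NCR-NU mice, cancer-free (Matrigel control) or tumour-bearing, directly into lysis buffer. Total RNA was amplified with a whole-transcriptome system, labelled with biotin and hybridised to 1-colour arrays. The labels give 14 biological replicates in 4 groups and 1 array each. The deposited values are on the log2 scale, made by RMA in the oligo package 1.32.0 under R 3.2.0 per the submitters' processing notes. Which arrays were normalised together, and whether a filter was applied, is not given in the sources used here. The scale itself is not written in the deposited table, but its range, 0.29 to 13.78, with no missing value, is that of log2 RMA values. The array build is not given, so no genome positions are printed.

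Of 41345 probes, 23521 carried 1 gene symbol, 1814 carried several and 16010 carried none. Of those with 1 symbol, 23328 had an Entrez identifier found in the mouse reference tables. For the 1082 genes with more than 1 probe the brightest on average was used, which gave 22180 genes. A gene was tested if it was above the median of the table (3.88) on at least 3 arrays, 3 being the smallest group, and 13805 genes passed. The 4 group means were fitted in limma 3.58.1 under R 4.3.3, with moderated variances without trend (residual degrees of freedom 10, prior degrees of freedom 3.86). There were 7 contrasts: tumour in young and in old mice, age in cancer-free and in tumour-bearing mice, the difference of the tumour effects between ages, and the averages for tumour and for age. P-values were adjusted by Benjamini and Hochberg within each contrast at 0.05, and tests were taken on both sides. Groups, contrasts, tests, gene lists and the rule for named genes were set before the data were examined.

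Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over lists within each contrast. Beside it, camera with an estimated correlation and fry were run, and an exact permutation of array labels within the groups compared was added after seeing the data. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. The 29 lists held markers of neutrophils, monocytes and macrophages, plasmacytoid and conventional dendritic cells, B cell progenitors, mature B cells, plasma cells, T cells, natural killer cells, group 2 innate lymphoid cells, erythroid cells, megakaryocytes and platelets, stem and progenitor cells, mesenchymal stromal cells and endothelial cells. They also held genes of MHC class II, the type I interferon and interferon gamma responses, NF-kappaB inflammation, the immediate early and heat shock responses, the unfolded protein response, the cell cycle, senescence and p53 targets, tumour-promoting secreted factors, the lysosome, oxidative phosphorylation and ribosomal proteins. Lists with at least 5 members tested were used, which left out basophil, mast cell and eosinophil markers (4 members tested), so 28 were tested. Areg and Grn were each in 2 lists, and no other gene was shared. In all 43 called shifts, the mean, the median and the test had 1 sign, while in 34 of 153 shifts not called they differed.

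Named genes were taken by rule. In each contrast these were the called genes with the highest and the lowest change and, where fewer than 10 passed, the genes with the smallest p up to 10, said not to pass. Predicted genes, olfactory and vomeronasal receptors and small RNA genes were counted but not named. For each list that was called or had a called member, up to 4 members with the smallest p were added. The rule also always included Ly6a, Kit, Ptprc and Grn, of which Ly6a, the gene of Sca1, was not analysed here. Junb, Ier2, Egr3, Il2ra, Itgax and Flt3 fall outside this rule and were named after their values were seen. Xist and the Y-linked genes served to check the sex given in the labels.

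The fit was tested on simulated data with 200 changed genes. A log2 change of 1 was recovered for 20.5% of genes for tumour in young mice, 41.5% for tumour in old mice, 34% for age in cancer-free mice, 32.5% for age in tumour-bearing mice, 65% and 61.5% for the tumour and age averages, and 0% for the difference by age. A change of 2 was recovered for 67% to 98%. Among 20 simulations of independent genes without a change, 0 had a called list. Genes of real arrays are correlated, and relabelled real arrays gave a median of 3 to 4 called lists per contrast.

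Alternatives for gene counts were no filter, a stricter filter (5.48), cyclic loess, median centring of each array, a variance trend with a robust prior, array weights, the mean of a gene's probes, all probes, only the groups compared, the replicate number as a block, and leaving out each array. Leaving out the 2 least correlated arrays, and the array's mean correlation as a covariate, were added after seeing the data. The labels do not say whether equal replicate numbers pair samples, and pairing was not established.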

Results

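The data are whole-transcriptome array profiles of bone marrow cells that carry the surface marker Sca1 and lack the receptor Kit, sorted by flow cytometry from female nude (NCR-NU) mice, a strain without a thymus. The mice were young or old, and either cancer-free, carrying a Matrigel plug as the control, or bearing a primary tumour matched in size between the ages. There were 3 young cancer-free, 3 young tumour-bearing, 5 old cancer-free and 3 old tumour-bearing mice, with 1 array each, 14 arrays in all. Of 22180 named genes, 13805 were bright enough to test. The array medians lay between 3.81 and 3.93 on the log2 scale, and the median within-group SD of a gene was between 0.23 and 0.32. The number of arrays limits the precision. The Y-linked genes Eif2s3y, Kdm5d and Uty stayed between 1.67 and 2.73 on all arrays while Xist lay between 10.37 and 11.35, and the labels give female mice. Each array's mean correlation with the other 13 was lowest for young tumour-bearing replicate 1 (0.899), old tumour-bearing replicate 3 (0.907) and old tumour-bearing replicate 2 (0.910), and highest for young cancer-free replicate 1 (0.942). For Adgrg1, Spdl1, Bub1, Esco2, Trim12c, Naip6, Col10a1 and Cxcl1 at least 1 group mean was under the floor of 3.88 used for dim genes, so the differences given for them are not exact sizes. In what follows a gene or list is called at an adjusted p under 0.05, and changes are log2 differences ± SE.

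The first question was how marrow cells of this phenotype differ between old and young hosts, averaged over cancer-free and tumour-bearing mice. In limma 12 genes were called, 10 lower and 2 higher in old mice. Csn3, the milk protein kappa-casein, rose by 1.67 ± 0.19 (3.19-fold, adjusted p = 0.00881 in limma). Its level was 4.05 ± 0.21 (SD, n = 3) in young cancer-free and 4.11 ± 0.16 (SD, n = 3) in young tumour-bearing mice. It was 5.46 ± 0.46 (SD, n = 5) in old cancer-free and 6.05 ± 0.43 (SD, n = 3) in old tumour-bearing mice. Sgsm3, a regulator of small GTPases, rose by 0.87 ± 0.15. The young arrays lay near the floor of 3.88 used for dim genes, at 3.89 to 4.29 for Csn3 and 3.86 to 4.50 for Sgsm3. Neither difference is therefore an exact size. Among the genes that fell, Kif23 (-1.66 ± 0.24), a kinesin of cytokinesis, Nuf2 (-1.57 ± 0.27), a kinetochore protein, and Spdl1 (-1.45 ± 0.20), a mitotic dynein adaptor, act in cell division. Hells (-1.25 ± 0.19) encodes a chromatin remodeller of proliferating cells. The others were Fam91a1 (-1.23 ± 0.20), the adhesion receptor Adgrg1 (-1.14 ± 0.18, with old arrays at 3.58 to 3.91, around that floor), the glycosyltransferase Mgat5 (-1.01 ± 0.14), the myeloid integrin Itgam (-0.96 ± 0.15), the adhesion molecule Pecam1 (-0.92 ± 0.15) and Sec14l1 (-0.88 ± 0.15). Most falls were larger in tumour-bearing than in cancer-free mice. Sec14l1 was at -1.43 and -0.34, Adgrg1 at -1.70 and -0.59, Nuf2 at -2.15 and -0.99, and Hells at -1.67 and -0.82, in that order. Only Itgam fell more in cancer-free mice (-1.02, against -0.90). Limma called 0 genes for the difference of the tumour effects between ages, which equals the difference between these age effects. Of the 12 genes, 5 (Csn3, Sgsm3, Spdl1, Pecam1 and Sec14l1) had all 8 old arrays on one side of all 6 young arrays. As the genes were picked for their difference on these same arrays, this is not separate support. For Sec14l1 the highest old array was at 5.503 and the lowest young array at 5.508. At unadjusted p under 0.05 there were 1851 genes, 613 higher and 1238 lower, with 690.25 expected by chance. How far such counts, and the shares without overlap given below, vary by chance among correlated genes was not tested.

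**Figure D1:**
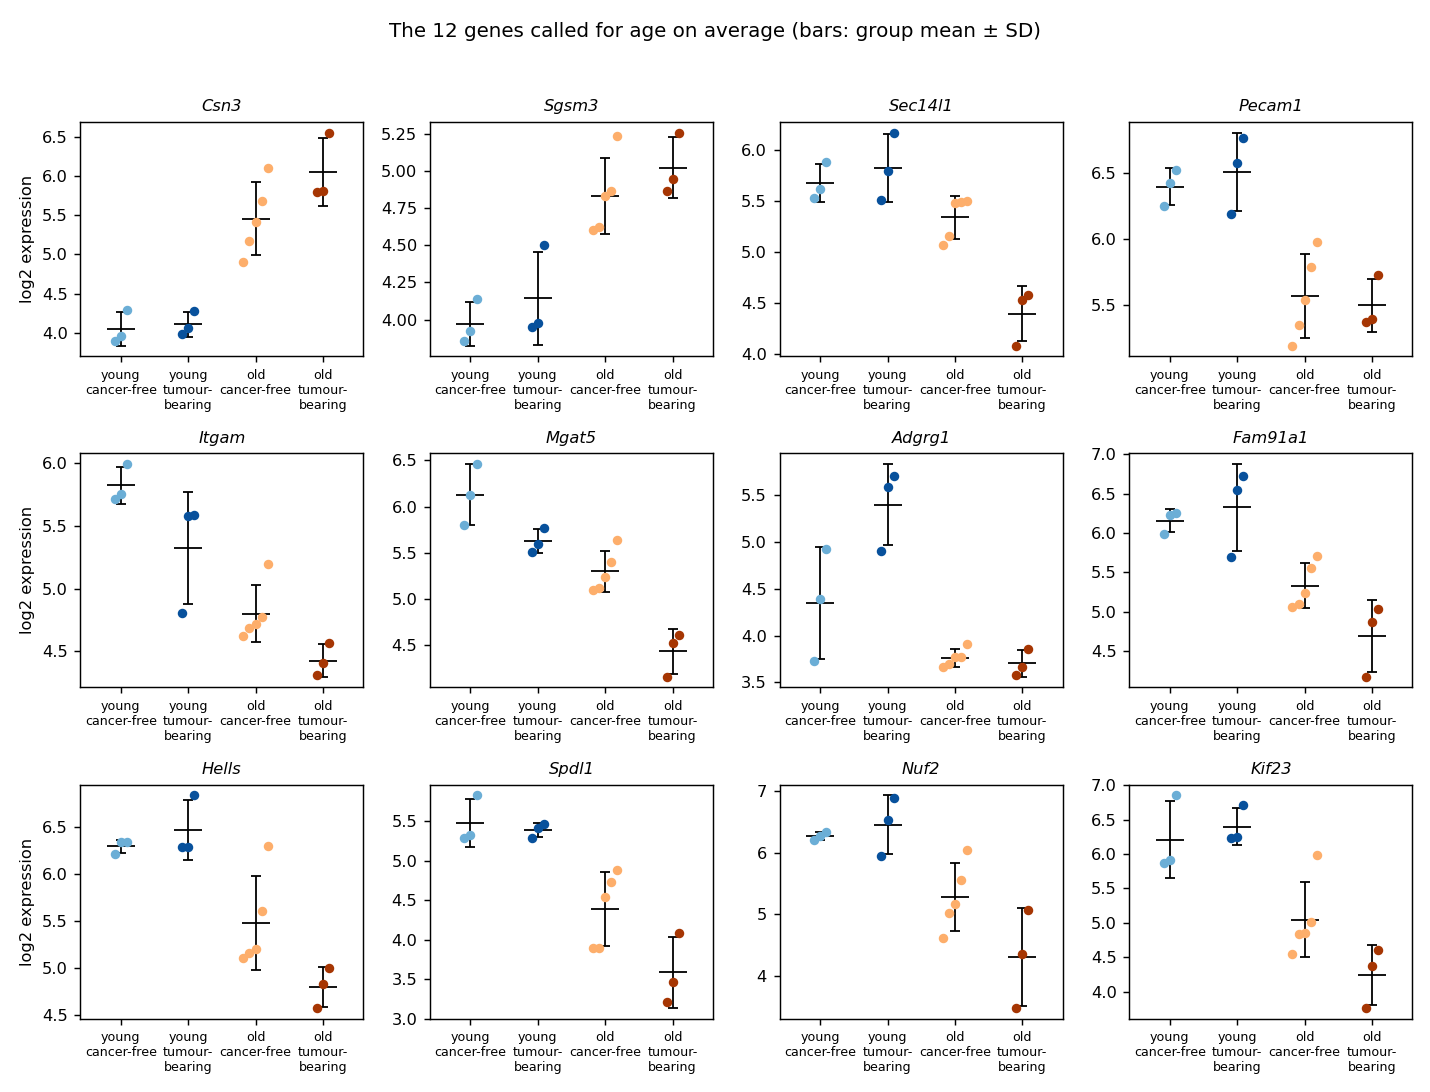
Each panel shows the log2 expression of 1 of the 12 genes called for age on average, with a point per array and bars for the group mean ± SD, in young cancer-free (n = 3), young tumour-bearing (n = 3), old cancer-free (n = 5) and old tumour-bearing (n = 3) mice. Csn3 was between 4.91 and 6.55 in old and between 3.89 and 4.29 in young mice.

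Among the gene lists fixed in advance, camera called 7 of 28 for age on average. The cell cycle list was lower in old mice: all 23 members had a negative difference and the list mean was -0.93 ± 0.21 (adjusted p = 5.55e-16 with the preset correlation, but adjusted p = 0.281 with an estimated correlation). All 8 old arrays had a list mean below those of all 6 young arrays. Of its members 19 were lower when adjusted over the list alone and 0 when adjusted over all genes. Examples are Mki67 (-1.53 ± 0.29), a marker of cycling cells, Top2a (-1.50 ± 0.30), the topoisomerase of dividing cells, Bub1 (-1.21 ± 0.23), a spindle checkpoint kinase, and the replication helicase subunit Mcm3 (-1.32 ± 0.24). In fry, limma's rotation test, the list had adjusted p = 0.0205. An exact permutation of array labels, taken on both sides, gave p = 0.00268 (adjusted p = 0.0625). All 15 plasmacytoid dendritic cell markers were lower in old mice too, with a mean of -0.997 ± 0.27 and 8 members lower adjusted over the list alone. This list had adjusted p = 0.398 with an estimated correlation and exact permutation p = 0.00446 (adjusted p = 0.0625). Siglech, a surface receptor of these cells, was at -1.46 ± 0.34, Cox6a2 at -1.57 ± 0.31, the transcription factor Spib at -2.14 ± 0.54 and the RNA sensor Tlr7 at -1.13 ± 0.26.

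The immediate early list, of genes induced within minutes of a stimulus, was higher in old mice by 0.50 ± 0.18 (adjusted p = 0.454 with an estimated correlation; 0.75 ± 0.24 in cancer-free and 0.24 ± 0.27, not called, in tumour-bearing mice). Adjusted over the list alone, 6 members were higher and 1 lower. The higher ones were Fos (1.97 ± 0.43), Jun (1.49 ± 0.33), Fosb (1.78 ± 0.42) and Junb, which are subunits of AP-1, with Zfp36 (0.81 ± 0.17) and Ier2. The lower one was Egr3 (-0.69 ± 0.23). T cell markers were higher by 0.48 ± 0.20 (10 of 13 members higher, 0 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation). Their difference was 0.06 ± 0.26, not called, in cancer-free and 0.89 ± 0.29 in tumour-bearing mice. MHC class II genes, of antigen presentation, were lower by -0.45 ± 0.14 (8 of 9 members lower, 5 adjusted over the list alone, adjusted p = 0.398 with an estimated correlation). They were at -0.23 ± 0.18, not called, in cancer-free and -0.68 ± 0.20 in tumour-bearing mice. The list mean was 5.45 in old tumour-bearing mice, against 6.08 in old cancer-free, 6.12 in young tumour-bearing and 6.30 in young cancer-free mice. Every MHC class II call, for age or for tumour, includes the old tumour-bearing group, so these calls are not separate results. H2-Eb2 was at -0.88 ± 0.24 and H2-DMa at -0.63 ± 0.17. Monocyte and macrophage markers were lower by -0.44 ± 0.15 (11 of 14 lower, 4 adjusted over the list alone, adjusted p = 0.431 with an estimated correlation). The chemokine receptors Cx3cr1 and Ccr2 were at -0.76 ± 0.26 and -0.56 ± 0.19. The unfolded protein response list was higher by 0.16 ± 0.11 (11 of 14 higher, 0 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation), at 0.19 ± 0.14 in cancer-free and 0.13 ± 0.16, not called, in tumour-bearing mice. The chaperone Hspa5 was at 0.53 ± 0.18 and Ddit3 at 0.72 ± 0.25.

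The number of called genes was 74 without old tumour-bearing replicate 3, 19 without old cancer-free replicate 1, and 6 without young cancer-free replicate 1 or 2. It was 4 without old tumour-bearing replicate 2, 3 without old cancer-free replicate 2 or 5 or old tumour-bearing replicate 1, and 2 without old cancer-free replicate 4 or young tumour-bearing replicate 3. It was 1 without young tumour-bearing replicate 1 and 0 in limma without young cancer-free replicate 3 (1592 at unadjusted p under 0.05). The unfolded protein response call was lost, with a list mean of 0.09 to 0.16, without old cancer-free replicate 1 or 5, old tumour-bearing replicate 1 or 3, young cancer-free replicate 3 or young tumour-bearing replicate 3, and without a filter on dim genes (0.16) or the 2 least correlated arrays (0.15). Over the alternatives, the calls of the 10 genes that the naming rule took here were lost in 2 of 24 (Csn3) to 18 of 24 (Nuf2) runs.

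**Figure D2:**
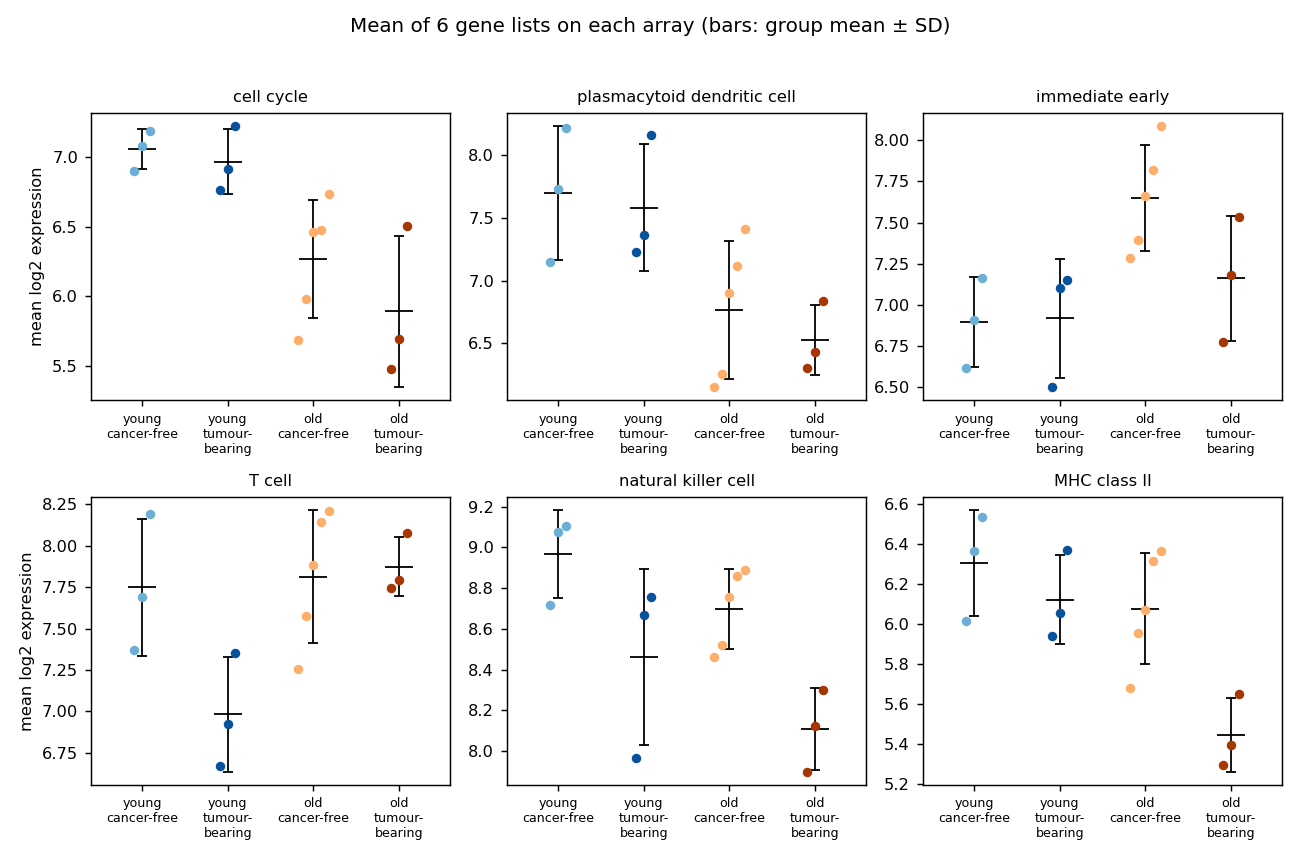
Each panel shows the mean log2 expression of 1 gene list on each array, as a point, with the group mean ± SD, in the 4 groups (n = 3 young cancer-free, 3 young tumour-bearing, 5 old cancer-free, 3 old tumour-bearing). The cell cycle list had a mean of 7.05 in young cancer-free and 5.89 in old tumour-bearing mice, and the natural killer cell list 8.97 and 8.11.

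In cancer-free mice alone, old hosts (n = 5) had more immediate early transcripts and fewer cell cycle and plasmacytoid dendritic cell transcripts than young hosts (n = 3) as lists, while 0 single genes were called. Each of these 3 list calls was lost with an estimated correlation (adjusted p = 0.388 with an estimated correlation). The immediate early list was higher by 0.75 ± 0.24, with 8 of 17 members higher and 1 lower adjusted over the list alone. Its mean was 7.65 in old cancer-free mice, against 6.90 in young cancer-free, 6.92 in young tumour-bearing and 7.16 in old tumour-bearing mice. Every call of this list, for age or for tumour, includes the old cancer-free group, so these calls are not separate results. Fos was at 8.29 ± 0.77 (SD, n = 5) in old and 5.71 ± 1.03 (SD, n = 3) in young cancer-free mice, a difference of 2.59 ± 0.57 (adjusted p = 0.393 in limma). Fosb differed by 2.65 ± 0.56, Jun by 2.002 ± 0.44 and Zfp36, which destabilises cytokine mRNAs, by 1.06 ± 0.22. The cell cycle list was lower by -0.79 ± 0.28 (21 of 23 members lower, 2 adjusted over the list alone) and the plasmacytoid dendritic cell list by -0.93 ± 0.36 (15 of 15 lower, 3 adjusted over the list alone). Camera also called the oxidative phosphorylation list as lower (-0.33 ± 0.17, 23 of 23 lower, adjusted p = 0.564 with an estimated correlation). The same held for the lysosome list (-0.26 ± 0.10, 14 of 16 lower, adjusted p = 0.388 with an estimated correlation). It held too for the monocyte and macrophage list (-0.43 ± 0.19, 11 of 14 lower, adjusted p = 0.448 with an estimated correlation). The unfolded protein response list was called higher (0.19 ± 0.14, 9 of 14 higher, adjusted p = 0.765 with an estimated correlation). Adjusted over the list alone, 1 monocyte and macrophage member (Itgam) was lower, 2 unfolded protein response members (Ddit3 and Atf4) were higher, and 0 passed in the other 2 lists.

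The single genes with the smallest p in this comparison, none of which passed, each had adjusted p = 0.393 in limma. They were Csn3 (1.41 ± 0.26), Itgam (-1.02 ± 0.20), the host RNA Snhg1 (1.26 ± 0.25), the cell cycle genes Cdkn3 (-1.45 ± 0.29), Esco2 (-0.98 ± 0.20) and E2f3 (-1.67 ± 0.35). The others were Fosb, Zfp36, the glycolytic enzyme Tpi1 (-0.79 ± 0.17) and Tlr7 (-1.59 ± 0.34). The test found 1057 genes at unadjusted p under 0.05, 343 higher and 714 lower. In all, 1008 genes (7.30%) had no overlap between the groups, where chance gives 3.57%. The exact permutation, over 56 labellings, called 0 lists, with 1 at unadjusted p under 0.05 (immediate early, p = 0.0357), and fry 0. Calls were lost for the monocyte and macrophage list without old cancer-free replicate 4 (-0.37) or young cancer-free replicate 3 (-0.35), and for the lysosome list without old cancer-free replicate 3 or 4 or young cancer-free replicate 1 (all -0.22). The unfolded protein response call was lost without old cancer-free replicate 1, 2 or 5 or young cancer-free replicate 3 (0.04 to 0.19), and without a filter on dim genes or the 2 least correlated arrays (0.19 in both). The oxidative phosphorylation call was lost with each array's mean correlation as a covariate (-0.15), and the lysosome call with cyclic loess (-0.13).

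In tumour-bearing mice, old hosts (n = 3) again had fewer cell cycle and plasmacytoid dendritic cell transcripts than young hosts (n = 3), and more T cell transcripts. All 3 list calls were lost with an estimated correlation (adjusted p = 0.348 with an estimated correlation). The cell cycle list was lower by -1.07 ± 0.31 (23 of 23 members lower, 12 adjusted over the list alone). Ccna2, a cyclin of S and G2 phase, was at 5.74 ± 0.97 (SD, n = 3) in old and 8.02 ± 0.37 (SD, n = 3) in young mice. The plasmacytoid dendritic cell list was lower by -1.06 ± 0.40 (15 of 15 lower, 4 adjusted over the list alone). Spib was at -2.99 ± 0.80, Siglech at -1.90 ± 0.50 and the DNA sensor Tlr9 at -1.37 ± 0.42. T cell markers were higher by 0.89 ± 0.29 (11 of 13 higher, 7 adjusted over the list alone). Their list mean was 6.98 in young tumour-bearing mice, against 7.75 in young cancer-free, 7.81 in old cancer-free and 7.87 in old tumour-bearing mice. Every T cell call, for age or for tumour, includes the young tumour-bearing group, so these calls are not separate results. The coreceptor chain Cd8a was at 1.99 ± 0.59, Cd3e at 1.17 ± 0.37, Themis at 1.39 ± 0.46 and Cd5 at 1.65 ± 0.59. MHC class II genes were lower by -0.68 ± 0.20 (8 of 9 lower, 4 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation), with H2-Eb2 at -1.50 ± 0.36 and H2-Oa at -1.20 ± 0.35. The neutrophil list was lower by -0.58 ± 0.43 (16 of 19 lower, 0 adjusted over the list alone, adjusted p = 0.784 with an estimated correlation), with the granule enzyme Mpo at -2.05 ± 0.58. The monocyte and macrophage list was lower by -0.45 ± 0.22 (12 of 14 lower, 1 adjusted over the list alone, adjusted p = 0.528 with an estimated correlation).

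Limma called 0 single genes between old and young tumour-bearing mice, with a smallest adjusted p of 0.0540. There were 1394 genes at unadjusted p under 0.05, 518 higher and 876 lower. The leading genes, none of which passed, were Csn3 (1.94 ± 0.29), Sec14l1 (-1.43 ± 0.22), Nop16 (2.04 ± 0.32), a ribosome assembly factor, Cryba4 (1.35 ± 0.22), Ugdh (-1.57 ± 0.25) and Adgrg1 (-1.70 ± 0.27), each with adjusted p = 0.0540 in limma. Next came Spdl1 (-1.80 ± 0.30), Kif23 (-2.15 ± 0.36), Hells (-1.67 ± 0.28) and the granzyme Gzmm (1.51 ± 0.27). Groups did not overlap for 1800 genes (13.04%, chance 10%). Other settings called up to 9 genes here, and 2 were called without old tumour-bearing replicate 3. With 3 arrays against 3, an exact permutation cannot give a p below 0.1, which is what all 6 lists had. It called 0 lists, and fry 0. The neutrophil call was lost without old tumour-bearing replicate 1 (-0.41) or young tumour-bearing replicate 1 (-0.32). The monocyte and macrophage call was lost without either of these (-0.31 and -0.43) or old tumour-bearing replicate 2 (-0.41). Cyclic loess ended the latter (-0.43), leaving out the 2 least correlated arrays ended the former (-0.44), and the number of called lists was 10 without young tumour-bearing replicate 3.

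**Figure D3:**
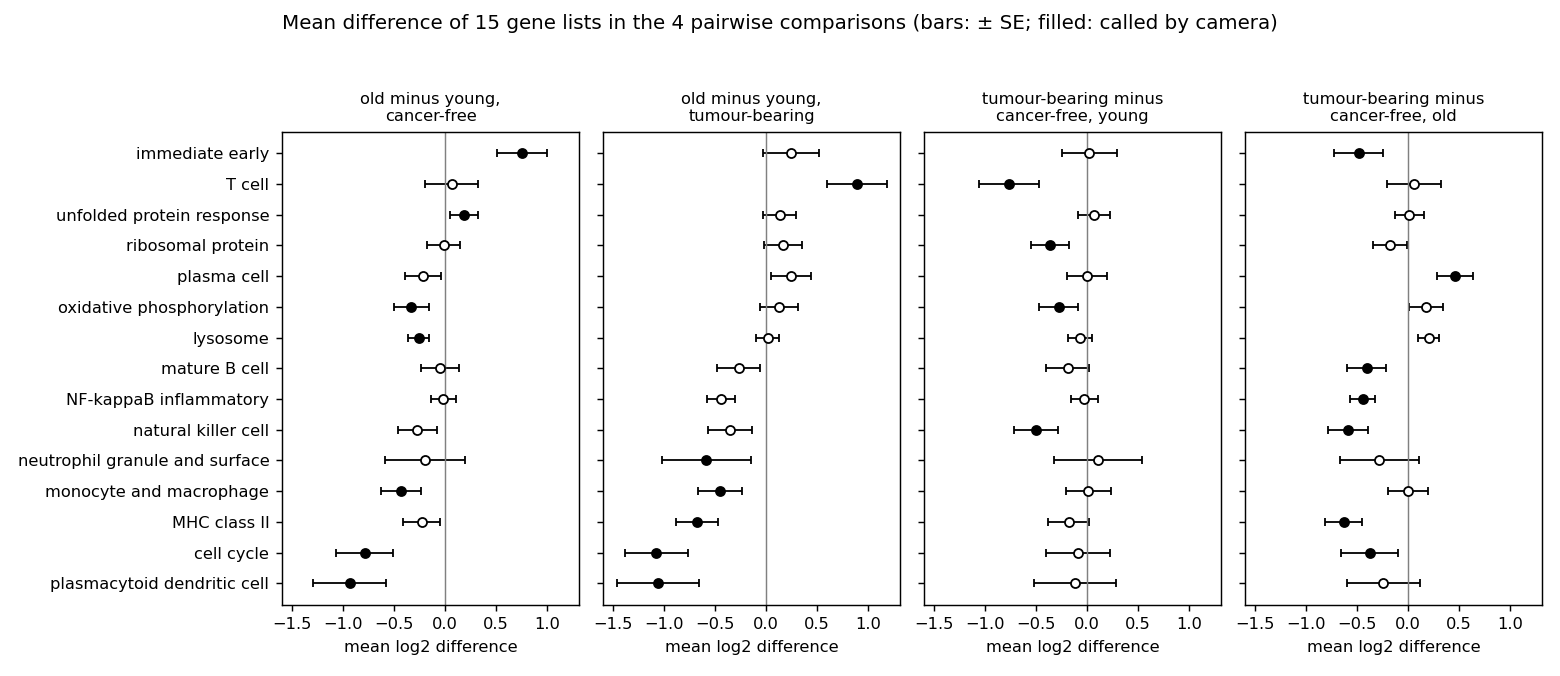
The 4 panels give the mean log2 difference ± SE of the 15 gene lists called in at least 1 contrast, for old minus young and for tumour-bearing minus cancer-free mice, with filled points for lists called by camera in that comparison. The cell cycle list lay at -0.79 and -1.07 for age, and at -0.09 and -0.38 for tumour.

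The second question was how these marrow cells differ between tumour-bearing and cancer-free hosts. In young mice, tumour-bearing hosts (n = 3) had lower levels of T cell and natural killer cell markers than cancer-free hosts (n = 3). Both list calls were lost with an estimated correlation (adjusted p = 0.479 with an estimated correlation), and that of natural killer cells also without young tumour-bearing replicate 1 (-0.26). All 13 T cell markers were lower, with a list mean of -0.77 ± 0.29 (0 members adjusted over the list alone). Cd3d, a chain of the T cell receptor complex, was at 7.73 ± 1.53 (SD, n = 3) in tumour-bearing and 9.42 ± 0.35 (SD, n = 3) in cancer-free mice, a difference of -1.69 ± 0.57. Cd3e differed by -0.99 ± 0.37. Of 16 natural killer cell markers 15 were lower, with a mean of -0.50 ± 0.22. The receptor Klrc1 was at -1.15 ± 0.44 and the transcription factor Tbx21 at -0.67 ± 0.25. The ribosomal protein list was lower by -0.36 ± 0.18 (16 of 19 lower), with Rplp0 at -0.97 ± 0.33, and the oxidative phosphorylation list by -0.28 ± 0.19 (20 of 23 lower). They had adjusted p = 0.479 and adjusted p = 0.723 with an estimated correlation. In these 2 lists and the natural killer cell list, too, 0 members passed adjusted over the list alone.

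Limma called 0 single genes for tumour in young mice (smallest adjusted p = 0.494, 745 at unadjusted p under 0.05 of which 290 were higher and 455 lower). The leading genes, none of which passed, were Kbtbd2 (-0.94 ± 0.16), Klk8 (-1.63 ± 0.33), Parvb (1.72 ± 0.36), Slc35a5 (-1.27 ± 0.29), and Clec2i (-1.40 ± 0.33). The others were the mitochondrial fusion gene Opa1 (-0.84 ± 0.20), Ccnq (-1.63 ± 0.39), Rcn1 (-1.50 ± 0.36), Zfp60 (-1.13 ± 0.28) and Syt12 (0.70 ± 0.18). Here 1785 genes (12.9%) had no overlap between the groups, against 10% by chance. The exact permutation, which cannot go below 0.1 here, and fry called 0 lists. Without young tumour-bearing replicate 1, the array with the lowest mean correlation, 1 list was called, T cell (-0.74). The natural killer cell (-0.26), ribosomal protein (-0.12) and oxidative phosphorylation (-0.03) lists did not pass, the last also not without young cancer-free replicate 2 (-0.23) or with cyclic loess (-0.18). With each array's mean correlation as a covariate the same 3 calls were lost, at -0.20, -0.0612 and -0.00408.

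In old mice, tumour-bearing hosts (n = 3) had fewer natural killer cell and MHC class II transcripts and more plasma cell transcripts than cancer-free hosts (n = 5), and on all 3 of their arrays these list means lay outside the cancer-free range. All 3 list calls were lost with an estimated correlation (adjusted p = 0.292 with an estimated correlation). The natural killer cell list was lower by -0.59 ± 0.19 (15 of 16 lower, 2 adjusted over the list alone). The lectin receptor Klri2 was at 4.69 ± 0.66 (SD, n = 3) in tumour-bearing and 6.82 ± 0.78 (SD, n = 5) in cancer-free mice (-2.13 ± 0.61), and Klrk1 differed by -1.02 ± 0.30. MHC class II genes were lower by -0.63 ± 0.18 (9 of 9 lower, 4 adjusted over the list alone), with H2-Oa at -1.45 ± 0.32 and H2-Aa at -1.08 ± 0.40. All 12 plasma cell genes were higher, by 0.46 ± 0.17 on average (1 adjusted over the list alone). The receptor Tnfrsf13b was at 0.90 ± 0.21, Sdc1, the plasma cell marker CD138, at 0.42 ± 0.17 and the secretory regulator Xbp1 at 0.37 ± 0.19. The NF-kappaB inflammatory list was lower by -0.45 ± 0.12 (10 of 13 lower, adjusted p = 0.292 with an estimated correlation). Adjusted over the list alone, 2 cytokine genes were lower, Tnf (-1.17 ± 0.32) and Ccl4 (-1.21 ± 0.36), and 1 was higher, Cxcl1 (0.78 ± 0.22). The mature B cell list was called lower (-0.41 ± 0.19, 9 of 13 lower, 2 adjusted over the list alone, adjusted p = 0.481 with an estimated correlation), with Cd22 at -1.22 ± 0.32. So was the immediate early list (-0.49 ± 0.24, 16 of 17 lower, 0 adjusted over the list alone, adjusted p = 0.481 with an estimated correlation), with Egr1 at -1.46 ± 0.46. So was the cell cycle list (-0.38 ± 0.28, 21 of 23 lower, 0 adjusted over the list alone, adjusted p = 0.497 with an estimated correlation), with Tk1 at -0.93 ± 0.26.

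Limma called 0 single genes for tumour in old mice, with a smallest adjusted p of 0.0801. There were 1348 genes at unadjusted p under 0.05, 580 higher and 768 lower. The leading genes, none of which passed, were the glycosyltransferase B3gnt5 (-1.65 ± 0.23), Ugdh (-1.45 ± 0.22), the RNA methyltransferase Trmt2a (-1.27 ± 0.21), the RNA acetyltransferase Nat10 (-1.22 ± 0.21), and Tia1 (-1.15 ± 0.21). The others were Pbx2 (-1.55 ± 0.28), Fastk (-1.14 ± 0.21), Adgrl2 (1.28 ± 0.24), Ralb (1.55 ± 0.29) and Il10ra (-1.70 ± 0.33), a receptor chain for interleukin-10. Groups did not overlap for 849 genes (6.15%, chance 3.57%). Leaving out old tumour-bearing replicate 1, old cancer-free replicate 3 or old cancer-free replicate 5 gave 4, 3 and 1 called genes. In the exact permutation over 56 labellings, 5 lists had an unadjusted p under 0.05. The smallest exact p was p = 0.0179 for natural killer cells, the smallest it can give, and 0 lists passed adjustment, as with fry. Calls were lost without old tumour-bearing replicate 3 for the mature B cell (-0.31), NF-kappaB (-0.36) and immediate early (-0.29) lists, leaving 4 lists. They were lost without old cancer-free replicate 2 for the same 3 (-0.34, -0.40 and -0.38), without old cancer-free replicate 3 (-0.35) or old tumour-bearing replicate 2 (-0.41) for mature B cell, and without old tumour-bearing replicate 1 for cell cycle (-0.17). With each array's mean correlation as a covariate the mature B cell (-0.27) and NF-kappaB (-0.44) calls were lost.

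Averaged over both ages, tumour-bearing mice had fewer natural killer cell transcripts: all 16 markers were lower and the mean was -0.55 ± 0.15. This list had adjusted p = 0.414 with an estimated correlation and exact permutation p = 0.00268 (adjusted p = 0.0750). Adjusted over the list alone 7 members passed, among them Klri2 (-1.68 ± 0.46), Klrk1 (-0.70 ± 0.23), the activating receptor Ncr1 (-0.82 ± 0.27) and Klrc1 (-0.88 ± 0.30). MHC class II genes were lower by -0.41 ± 0.14 (9 of 9 lower, 1 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation), at -0.18 ± 0.20, not called, in young and -0.63 ± 0.18 in old mice. The plasma cell list was higher by 0.23 ± 0.13 (12 of 12 higher; -0.000469 ± 0.20 in young and 0.46 ± 0.17 in old mice), the ribosomal protein list lower by -0.27 ± 0.12 (19 of 19 lower; -0.36 ± 0.18 in young and -0.18 ± 0.17 in old mice) and the T cell list lower by -0.35 ± 0.20 (11 of 13 lower; -0.77 ± 0.29 in young and 0.06 ± 0.26 in old mice), each with adjusted p = 0.418 with an estimated correlation. The cell cycle list was lower by -0.23 ± 0.21 (20 of 23 lower, adjusted p = 0.549 with an estimated correlation), at -0.09 ± 0.31 in young and -0.38 ± 0.28 in old mice. In these 4 lists 0 members passed adjusted over the list alone. Limma called 0 genes (1414 at unadjusted p under 0.05, 584 higher and 830 lower). The leading ones, each with adjusted p = 0.268 in limma, were Lgmn (0.93 ± 0.16), a lysosomal protease, Abhd13 (-0.97 ± 0.17), B3gnt5 (-0.91 ± 0.17), Trmt2a (-0.80 ± 0.16), and Kbtbd2 (-0.52 ± 0.11). The others were Stap1 (-0.85 ± 0.18), Clec2i (-1.06 ± 0.22), Hmgcs1 (-1.08 ± 0.22), a sterol synthesis enzyme, Trim12c (-1.15 ± 0.24) and Mgat5 (-0.69 ± 0.14). The ribosomal protein call was lost without young tumour-bearing replicate 1 (-0.15), the plasma cell call without young tumour-bearing replicate 2 (0.16) and the T cell call without young tumour-bearing replicate 3 (-0.28). The cell cycle call was lost, at -0.13 to -0.22, without old cancer-free replicate 2 or 3, old tumour-bearing replicate 1 or 2, young cancer-free replicate 1, or young tumour-bearing replicate 1 or 2, and with cyclic loess (-0.16), and without young cancer-free replicate 2 the number of called lists was 10. With each array's mean correlation as a covariate the ribosomal protein (-0.0255), T cell (-0.13) and MHC class II (-0.31) calls were lost, the first also without the 2 least correlated arrays (-0.13).

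Whether the tumour effect differed between ages was tested by the difference of both tumour effects, old minus young. The T cell list had a difference of 0.83 ± 0.39, positive for 13 of 13 members, as its tumour effect was -0.77 ± 0.29 in young and 0.06 ± 0.26 in old mice (adjusted p = 0.598 with an estimated correlation). The oxidative phosphorylation list had a difference of 0.46 ± 0.25 (20 of 23 positive) and the plasma cell list of 0.46 ± 0.26 (10 of 12 positive), each with adjusted p = 0.598 with an estimated correlation. The immediate early (-0.51 ± 0.37, 15 of 17 negative), NF-kappaB inflammatory (-0.42 ± 0.18, 10 of 13 negative) and cell cycle (-0.29 ± 0.42, 16 of 23 negative) lists went the other way. Camera called these 6 lists, but they had adjusted p = 0.598 to 0.848 with an estimated correlation. In the exact permutation 0 lists had an unadjusted p under 0.05. For this contrast it exchanged tumour labels within each age, which tests for no tumour effect at either age. It is therefore not an exact test of a difference between ages. Adjusted over the list alone, 1 member passed, Tnfrsf13b of the plasma cell list (1.24 ± 0.32). Limma called 0 genes (smallest adjusted p = 0.736, 610 at unadjusted p under 0.05). The leading ones, none of which passed, were Rlf (-1.42 ± 0.28), Ralb (2.13 ± 0.44), Naip6 (-2.11 ± 0.44), Nop16 (2.08 ± 0.43), and Klk8 (2.11 ± 0.44). The others were Ugdh (-1.55 ± 0.34), Zfp961 (-1.29 ± 0.28), Adgrl2 (1.61 ± 0.35), Pgs1 (1.69 ± 0.39) and Col10a1 (1.57 ± 0.36). Without young tumour-bearing replicate 1 or old cancer-free replicate 2, 3 lists were called. The oxidative phosphorylation call was lost without the former (0.21), the plasma cell call without old tumour-bearing replicate 2 (0.42) or young tumour-bearing replicate 3 (0.40). The immediate early call was lost without 5 arrays (-0.32 to -0.42): old cancer-free replicate 2, old tumour-bearing replicate 3, young cancer-free replicate 2 and young tumour-bearing replicates 1 and 2. The NF-kappaB call was lost without 8 of the 14 arrays (-0.34 to -0.44): old cancer-free replicates 2, 3 and 4, old tumour-bearing replicates 2 and 3, young cancer-free replicate 2 and young tumour-bearing replicates 1 and 2. The cell cycle call was lost without 8 (-0.08 to -0.31): old cancer-free replicates 1, 2 and 3, old tumour-bearing replicates 1 and 2, young cancer-free replicate 2 and young tumour-bearing replicates 2 and 3. It was lost with cyclic loess (-0.33) and the covariate (-0.28), and the NF-kappaB call without a filter (-0.30) and with cyclic loess (-0.46). Without the 2 least correlated arrays the NF-kappaB (-0.30), immediate early (-0.22) and oxidative phosphorylation (0.20) calls were lost.

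Grn, the secreted growth factor granulin, was at 10.64 ± 0.18 (SD, n = 3) in young cancer-free, 10.96 ± 0.46 (SD, n = 3) in young tumour-bearing mice. It was at 10.01 ± 0.28 (SD, n = 5) in old cancer-free and 10.68 ± 0.13 (SD, n = 3) in old tumour-bearing mice. Its tumour difference was 0.67 ± 0.22 in old mice (adjusted p = 0.395 in limma, groups not overlapping) and 0.32 ± 0.24 in young mice. Its age difference was -0.63 ± 0.22 in cancer-free and -0.28 ± 0.24 in tumour-bearing mice, none of which passed. The difference of its tumour effects between ages was 0.35 ± 0.33. Of the sort markers, Kit, against which cells were selected, was at 5.88 ± 0.55 (SD, n = 3), 6.62 ± 0.48 (SD, n = 3), 5.50 ± 0.27 (SD, n = 5) and 6.004 ± 0.27 (SD, n = 3) in the same order. It had a tumour difference of 0.62 ± 0.20 on average (adjusted p = 0.379 in limma). The leukocyte marker Ptprc, which encodes CD45, lay between 10.57 and 10.99 in all 4 group means. Ly6a, the gene of Sca1, was not analysed here.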

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

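The splits of the samples and the test with plasmacytoid dendritic cell markers as a covariate were set before their results were seen, and every other test in this part was chosen after. For both array-quality tests and the stem and progenitor test the bound, too, was changed after their values were known, and the verdict changed with it. In old cancer-free mice 7 of 177 sets of 5 values had 1 array far from the other 4, where chance gives 8.85. The number given is that array's gap to its nearest neighbour divided by the range. It was 0.728 for Ddit3 (replicate 2 at 7.67, others 8.45 to 8.74), 0.736 for Itgam (replicate 1 at 5.196, others 4.62 to 4.77) and 0.748 for Nat10 (replicate 4 at 6.08, others 5.51 to 5.65). It was 0.824 for Rps3 (replicate 5 at 10.60, others 10.93 to 10.995), 0.712 for Tnfrsf13b (replicate 3 at 6.14, others 6.64 to 6.84) and 0.854 for Tpi1 (replicate 5 at 7.41, others 6.94 to 7.01). It was 0.751 for the erythroid list mean (replicate 1 at 4.87, others 4.33 to 4.46).

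Camera called the difference of the tumour effects, old minus young, for 6 lists, which had adjusted p = 0.598 to 0.848 with an estimated correlation. The smallest exact permutation p was p = 0.0652, and 0 lists passed adjustment there. That permutation exchanged labels within each age and is not an exact test of this difference. The differences were 0.83 for T cells, 0.46 for plasma cells, 0.46 for oxidative phosphorylation, -0.51 for immediate early genes, -0.42 for NF-kappaB inflammatory genes and -0.29 for the cell cycle. Probe 17341694, which has no listed gene, stood out among 9551 probes outside the gene tests. It was lower in tumour-bearing than in cancer-free old mice by -1.92 ± 0.21 (adjusted p = 0.0164 in limma) and lower in old than in young tumour-bearing mice by -1.96 ± 0.23 (adjusted p = 0.0434 in limma). Its group means were 8.44 ± 0.16 (SD, n = 3) and 8.31 ± 0.35 (SD, n = 3) in young, and 8.27 ± 0.29 (SD, n = 5) and 6.35 ± 0.19 (SD, n = 3) in old mice, cancer-free first. The difference of its tumour effects was -1.79 ± 0.31 (adjusted p = 0.862 in limma).

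Chance is argued against for the number of genes called for age on average, in the main setting only. Of 100 splits only 1, the real one, reached 12, and the highest other gave 0. That is the smallest share 100 splits can give, and the counts tested in this way were not corrected for their number. Other settings, for which no splits were run, gave 0 (replicate block) to 80 genes (median centring), and leaving out 1 array gave 0 to 74. For the number of lists called for age on average chance cannot be excluded, as 11 of 100 splits reached the real 7 (highest other 8). Nor can it for lists in the tumour average (24 of 100 reached 6, highest other 9), the difference by age (26 of 100 reached 6, highest other 11), tumour in old mice (8 of 56 reached 7, highest other 11) and age in cancer-free mice (9 of 56 reached 7, highest other 12). With 0 called genes, every split reached the real count: 56 of 56 for tumour in old mice (highest other 4) and for age in cancer-free mice (highest other 1), and 100 of 100 for the tumour average and the difference by age (highest other 1 in each). The splits for the difference by age exchanged tumour labels within each age. They assume no tumour effect at either age and so do not test the difference as such. With 3 arrays against 3 the splits are too few for a share under 0.05. For tumour in young mice the real split gave 0 genes and 4 lists, the highest other 0 and 8, and 10 and 5 of 10 splits reached these. For age in tumour-bearing mice it gave 0 genes and 6 lists, the highest other 2 and 8, and 10 and 2 of 10 splits reached these.

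In old mice the cell cycle list was lower (-0.93 ± 0.21). Array quality was judged only by each array's mean correlation with the others. That value comes from the same expression values and can also fall for a biologically distinct array, so it cannot decide on quality itself. With it as a covariate 10 of the 43 list calls were lost, while this list stayed called at -0.94 ± 0.25 (without the covariate, adjusted p = 0.281 with an estimated correlation). This argues against a lower mean correlation as the whole cause. Under the bound set first, more than 0.5 of the change kept by 2 errors, that too stays undecided. Fewer stem and progenitor cells stay open, although a sort against Kit would remove those that carry it: their list was at -0.12 ± 0.06, but 6 of 11 members were positive and 5 negative, and only 3 were above the stricter floor of 5.48 (under the bound set first, which ignored this, they were argued against). Fewer plasmacytoid dendritic cells could account for part, since with their markers as a covariate the change was -0.83 ± 0.34, whose error reaches the bound set beforehand. An effect of age itself stays open and untested.

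The immediate early list was higher in old than in young cancer-free mice (0.75 ± 0.24). Stress during handling may induce such genes, and heat shock genes, which it also induces, were at 0.17 ± 0.18, an error too wide to decide. Of the 10 heat shock members 4 were higher and 6 lower, and 1 of the higher ones passed adjusted over the list alone. With each array's mean correlation as a covariate the list stayed called at 0.79 ± 0.29 (without the covariate, adjusted p = 0.388 with an estimated correlation). This argues against a lower mean correlation as the whole cause, though under the bound set first that stays undecided here too. Array quality itself cannot be decided by this covariate. Age itself stays open and untested.

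Of the 4 lists lower in young tumour-bearing mice, 3 may rest on replicate 1 of that group, the array least correlated with the rest (all 4 calls were lost with an estimated correlation, with adjusted p = 0.723 for oxidative phosphorylation and adjusted p = 0.479 for the others). Without it, natural killer cell genes were at -0.26, ribosomal protein genes at -0.12 and oxidative phosphorylation genes at -0.0317, and none passed in camera. T cell genes stayed at -0.74, so that array is argued against as the cause of their difference. An effect of the tumour stays open and untested for all 4.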

How the results depend on the processing

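The exact permutation of labels, leaving out the 2 least correlated arrays and the covariate were chosen after the results were seen. No list shift reversed: of the 43 called, 0 held with an estimated correlation, 0 in the exact permutation and 1 in fry (cell cycle, age on average). With 3 arrays against 3 the exact p cannot go below 0.1, so no call there could hold. With 56 labellings it cannot go below 0.0179, and a list could pass adjustment only if many lists reached that at once. The permutation count therefore says little for the 4 pairwise comparisons. For the difference by age it is not an exact test, as labels were exchanged within each age. By comparison 40 held without a filter, 37 with cyclic loess, 33 with the covariate and 30 without the 2 arrays. The estimated correlation and the permutation called 0 lists in each of the 7 contrasts, and fry 0 in 6 and 1 in age on average. At unadjusted p under 0.05 the estimated correlation gave 1 to 4 lists per contrast and the permutation 0 to 8. The tumour average had 10 lists without a filter, tumour in young mice 1 without the 2 arrays and 1 with the covariate, and the difference by age 3 without the 2 arrays. The cause was not tested.

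For age on average, in place of 12 genes, 80 were called with median centring (12 shared), 57 with array weights (12 shared), 43 without the 2 arrays (7 shared) and 2 over all probes (1 shared). Without the 2 arrays Sgsm3, Hells, Fam91a1, Adgrg1 and Itgam were lost. For age in tumour-bearing mice in place of 0 genes there were 6 with loess, 9 with centring, 7 with the mean of probes, 1 over all probes and 6 without the 2 arrays, and for tumour in old mice 1 over all probes, in limma throughout. With centring the median change of all genes for age in cancer-free mice was -0.106, against -0.0389 without it. Leaving out 1 array gave 0 to 74 genes for age on average, 0 to 4 for tumour in old mice and 0 to 2 for age in tumour-bearing mice. It gave 1 to 5 lists for tumour in young mice, 4 to 9 for tumour in old mice, 5 to 8 and 5 to 10 for age in cancer-free and tumour-bearing mice, 3 to 9 for the difference by age, 5 to 10 for the tumour average and 6 to 9 for age on average. The cause was not tested.

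Of single gene values 5183 kept direction and side, 122 lost and 44 gained a call and 11 reversed, all of uncalled genes. Ptprc reversed for tumour in young mice with loess (0.00402), and for age on average with loess (0.0393), array weights (0.00842) and without the 2 arrays (0.00975). Leaving out 1 array gave -0.0694 to 0.00792 for it, and -0.498 to 0.0774 for the difference by age of Kit. Grn reversed for age in tumour-bearing mice without the 2 arrays (0.0362).

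Equal replicate numbers did not correlate (-0.0762 to 0.0887, 0 of 18 pairs over 0.1), so they were not taken as paired. Replicate numbers 4 and 5 occur only in old cancer-free mice, so a replicate block fits these arrays exactly and takes them out of the comparisons. Calls lost with the block can therefore not be put down to pairing. With it, age on average had 0 genes in limma and age in cancer-free mice 4 lists. Ptprc for age in cancer-free mice was at -0.0621, and 39 of the 43 list calls held. Those lost were, for age in cancer-free mice, monocyte and macrophage (-0.29), lysosome (-0.22) and oxidative phosphorylation (-0.20), and, for the difference by age, plasma cell (0.32). Signals near the floor of 3.88 limit what these arrays can show.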

Other observations

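Both correlation tests in this part were chosen after the result was seen. In 13 of the 28 lists camera called 0 shifts in limma, at any contrast. On average over ages, stem and progenitor genes were higher with a tumour by 0.16 ± 0.06 (8 of 11 members positive, exact permutation p = 0.00982, adjusted p = 0.11 there, camera adjusted p = 0.108). Type I interferon response genes were at -0.20 ± 0.07 (12 of 18 negative, exact permutation p = 0.0161, adjusted p = 0.11 there). Interferon gamma response genes were at -0.22 ± 0.09 (14 of 17 negative, exact permutation p = 0.0286, adjusted p = 0.133 there). Endothelial genes were at 0.13 ± 0.06, senescence and p53 target genes at 0.08 ± 0.03 (7 members positive and 7 negative) and tumour-promoting secreted factors at 0.08 ± 0.05. Group 2 innate lymphoid cell genes were at -0.32 ± 0.11 with a tumour in old mice (8 of 10 negative, exact permutation p = 0.0357, adjusted p = 0.2 there). Their member Il2ra, a chain of the interleukin-2 receptor, was at -1.35 ± 0.27.

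With age, on average over tumour states, conventional dendritic cell genes were at -0.34 ± 0.12 (8 of 10 negative, exact permutation p = 0.0161, adjusted p = 0.1 there). At unadjusted p under 0.05 only 2 members were lower, and 1 was higher. The 2 lower ones were Itgax, an integrin of dendritic cells, at -1.60 ± 0.33, and Flt3, a growth factor receptor, at -1.47 ± 0.30. The list mean thus rests largely on these 2 genes. B cell progenitor genes were at -0.15 ± 0.08, erythroid genes at -0.23 ± 0.14, mesenchymal stromal genes at -0.16 ± 0.11, megakaryocyte and platelet genes at 0.04 ± 0.05 and heat shock genes at 0.15 ± 0.13. None of these lists passed in camera.

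The tumour effects in young and in old mice, which share no array, had a Pearson r of 0.192 across 13805 genes, and the highest of 99 relabellings gave 0.115. Age effects in cancer-free and in tumour-bearing mice had r = 0.307, and the highest relabelling gave 0.232. A candidate explanation is a part of each effect that both settings share. Genes are not independent replicates, so these values carry no p of their own.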
